A study of Gallus gallus with 2 samples.

How the data were processed

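RNA from excised pieces of chick embryos was measured on 2 GeneChip Chicken Genome arrays, 1 for each tissue. Per the labels' protocols, embryos were incubated at 37.5 °C for about 12 h and electroporated at stage HH3 with a plasmid in which a 2.5 kb Cerberus upstream fragment drives EGFP, a green fluorescent protein. Pieces with EGFP fluorescence in the heart forming region (HFR), and the posterior end of the primitive streak (PPP), were then excised at HH4 to HH4+, while another label of the same samples gives HH4-5. Total RNA (45 ng, with poly-A control RNAs added) went through 2 rounds of amplification and was labelled with biotin, so each array has 1 colour.

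The values are probe set intensities on a linear scale that the authors deposited as model-based expression indices (MBEI). Per the series' design text, the authors normalized the arrays to a baseline array of median intensity with an invariant set of probes, and fitted a model to the perfect match probes of 6 arrays. These were the 2 arrays of the series and 4 arrays of another study. The 12 columns of those 4 arrays were not used here. GCOS 1.3 is named in the submitters' processing notes, and the program that fitted the model is not given in the sources used here. Per the file headers, each MBEI came with a detection call (present, marginal or absent) and a standard error. That error covers the spread among probes within 1 array and holds no biological variation. Because the scale was set by an invariant set of probes, a difference in total RNA per cell between the tissues is not measured.

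Each array held 38535 probe sets, of which 153 were control or reporter probe sets and 38382 were analysed. The series' value table held equal MBEI for 38535 of 38535 probe sets on each array. Gene symbols came from the platform annotation and were updated through Entrez gene IDs with a RefSeq gene table of assembly GRCg7b, used for names and chromosome classes alone. No coordinates are given, since the array values name no genome build. One symbol was listed for 27168 probe sets, several symbols for 177, and 11037 probe sets were not listed and are unnamed here. The gene ID of 26853 annotated probe sets was found in the RefSeq table. The 13009 genes were each represented by the probe set with the highest mean log2 MBEI, among probe sets with that symbol alone.

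The log2 difference between the arrays was computed as HFR minus PPP. A value listed at 0 (1 probe set, PPP array) was set to 0.1. A gene passed the level filter when its brighter array was called present and lay at or above 70.8 MBEI, the median over probe sets of the brighter array's value. In all, 7389 genes passed. Where the dimmer array was not called present, the fold is a lower bound, taken against the higher of the dim value and the lowest present MBEI of that array (6.5 on the HFR array and 4.8 on the PPP array). Their log2 differences are bounds in the same sense, and list medians hold such genes at those values. Among the named genes that floor replaced the measured value of IRX2, which is a member of no list, so no list median depends on it. The standard error of a log2 difference was propagated from the model errors of both arrays.

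With 1 array per tissue there is no replicate, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision. A difference was counted when it reached 2-fold. The rule for naming genes, the gene lists, the threshold and the level filter were chosen before the data were examined. The genes named are the 15 passing genes with the largest difference in each direction, leaving out bare locus, clone and EST names, then up to 4 passing members of each list by absolute difference with every member at 2-fold or more. CER1, TBXT and CCBE1 were named whatever their values. There were 23 lists, 13 of regions and pathways and 10 of other tissues and handling, and also the ribosomal protein genes taken by symbol prefix. The prefix also took in S6 kinase genes such as RPS6KB1. A list's median was set among medians of 10000 random lists of the same size, matched in 20 bins of mean level. That percentile is a description of these 2 arrays and is no test between tissues.

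Poly-A spike-ins were compared between the arrays, together with hybridization spike-ins and the 3 prime to 5 prime ratios of control transcripts. The alternatives were median centring, quantile normalization, a loess trend on level with a span of 0.3, a pseudocount of 22.3 MBEI, no level filter, a stricter filter at the 75th percentile, the median over a gene's passing probe sets, and leaving out probe sets with s, x or a suffixes. Thresholds of 1.5-fold and 4-fold, a difference over 2 standard errors, presence on both arrays, list means, and the series' value table were also tried. A further 3 settings were added after the data were seen, namely the highest passing probe set, a relative standard error under 30%, and poly-A spike-ins set equal.

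The procedure was tested on simulated data for 9442 genes with 200 genes changed 4-fold. It recovered 100% of them with 0 in the wrong direction, put 1 unchanged gene at 2-fold, and placed 98% of random lists inside their 95% range. The changed genes were drawn from bright genes alone, no detection call was required, and the noise had the size of the model errors within an array. Recovery of 4-fold changes at a 2-fold threshold was thus nearly fixed in advance. The result checks the computation and gives no error rate for these arrays. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.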

Results

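Gene expression was measured on 1 array of chick heart forming regions, selected by EGFP driven from a Cerberus fragment, and 1 array of the posterior part of the primitive streak. The heart forming region holds precursors of the heart, and the primitive streak is the site where mesoderm and endoderm leave the epiblast. The comparison addresses which genes differ between heart and hemangioblast precursors and the posterior streak. Of 38382 probe sets, 14744 (38.4%) were called present on the HFR array and 16190 (42.2%) on the PPP array. Median MBEI was 65.6 and 63, and among present probe sets the median model standard error was 4.71% and 4.18% of the MBEI. Every difference below rests on 1 array per tissue and has no replicate check. Errors after ± are model standard errors within an array.

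CER1 and TBXT, the genes named to check the labels, both lay opposite to them, CER1 with a wide error and TBXT under 2-fold. CER1, a secreted Nodal, BMP and Wnt antagonist whose regulatory fragment drove the EGFP, read 108.3 ± 19.2 MBEI on the HFR array, where its call was marginal, and 420.2 ± 193.3 on the PPP array, at least 3.88-fold higher. Its log2 difference was -1.96 with a standard error of 0.71. TBXT (Brachyury), a T-box factor of the streak and notochord, read 7128.6 ± 80.7 on the HFR array and 3691.4 ± 147.1 on the PPP array, 1.93-fold higher on the former. The arrays are therefore called HFR-labelled and PPP-labelled from here on, and each direction below is drawn between arrays for which these genes lay opposite to the labels. CCBE1, a secreted matrix protein, was called absent on both arrays with the probe set that stood for it (92.3 and 71.5 MBEI). Its other probe set read 26.6 (absent) and 229.5 MBEI (present), at least 8.63-fold higher on the PPP-labelled array.

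Among 7389 genes past the level filter, 285 were 2-fold or more higher on the HFR-labelled array and 314 on the PPP-labelled array, together 8.11%. On the less bright array, 62 of the 285 and 51 of the 314 were not called present. The median log2 difference was -0.05 with an SD across genes of 0.63, and log2 levels correlated across genes with a Pearson r of 0.93, where genes are not independent replicates. Of 151 genes at 2-fold with several passing probe sets, 142 (94.0%) had all of them in one direction, against 63.2% of all 2438 genes with several passing probe sets. That share was 55.2% without the level filter and 100% with the stricter one. Selecting by size on these same probe sets raises the share by itself, so the comparison is no check of the 2-fold genes. Setting the poly-A spike-ins equal, a scaling added after the data were seen, gave 6157 and 17 genes instead. A further 99 and 164 probe sets without a single gene symbol were 2-fold higher on the HFR-labelled and PPP-labelled array.

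**Figure D1:**
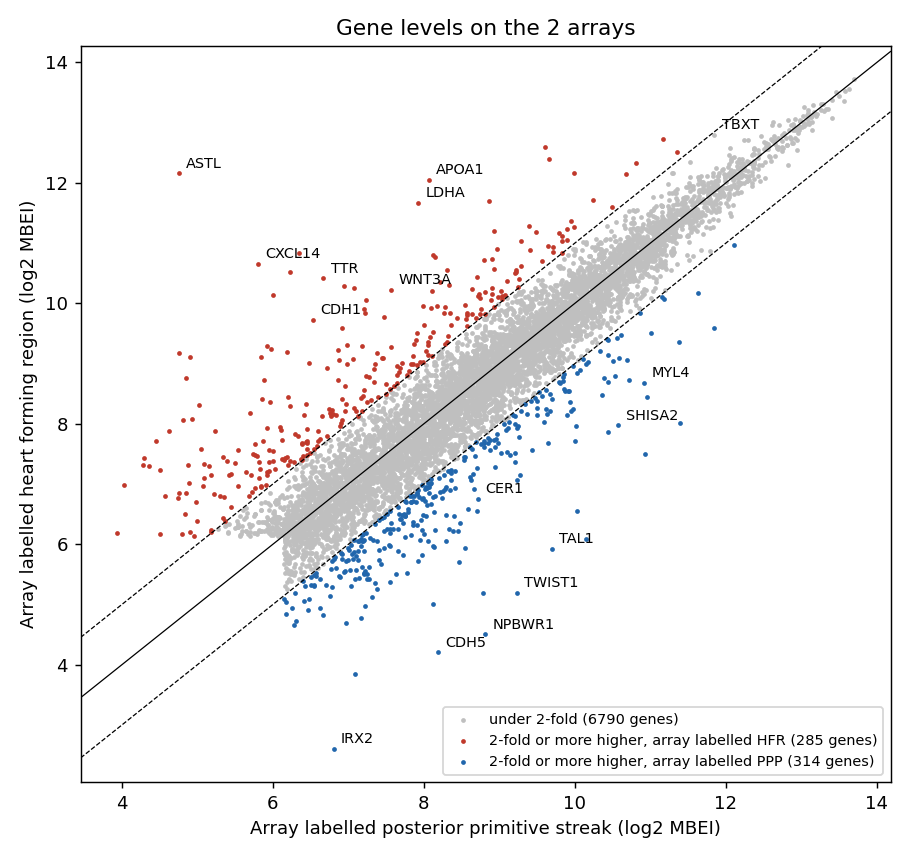
Log2 MBEI of genes past the level filter on the PPP-labelled array (horizontal) and the HFR-labelled array (vertical), 1 point per gene, with the line of equality and dashed lines at 2-fold. Red points (285 genes) and blue points (314 genes) lie outside the dashed lines, with ASTL far above them and CDH5, NPBWR1 and IRX2 far below.

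The largest difference toward the HFR-labelled array was ASTL, an astacin-family metalloprotease, at 4573.5 ± 384.5 MBEI against 27.1 ± 3.2 (absent), at least 169-fold. The chemokine CXCL14 read 1617.9 ± 203.8 against 55.8 ± 13.1, 29.0-fold higher. Carriers of retinol, thyroid hormone and lipid were among the 15 genes with the largest differences: RBP4A (22.6-fold), APOA1 (4249.7 ± 0.5 against 267.9 ± 8.4, 15.9-fold) and TTR (at least 13.4-fold). The APOA1 error of 0.5 is far under the median model error of 4.71% and is no measure of precision. The other passing APOA1 probe set read 3330.9 ± 456.9 against 311.5 ± 21 MBEI, 10.7-fold higher. The TTR value carried a wide error (1365.0 ± 511.7 MBEI), and with probe sets of relative error under 30% its log2 difference was 0.54 in place of 3.74. Epithelial membrane and junction genes were also present, with the uroplakins UPK1B (at least 18.3-fold) and UPK3BL (at least 17.7-fold) and the adherens junction protein PLEKHA7 (9.70-fold). LDHA, which interconverts pyruvate and lactate, was 13.3-fold higher at 3254.7 ± 430.9 against 243.9 ± 20 MBEI. The others were GPD1L2 (at least 21.5-fold), the actin-binding nebulette NEBL (19.5-fold), osteopontin SPP1 (at least 15.1-fold), the sodium-glucose transporter SLC5A1 (at least 10.3-fold), the growth factor PDGFA (10.1-fold) and the glucuronosyltransferase UGT1A1. UGT1A1 was at least 9.73-fold higher, with a log2 difference of 3.28 that was 1.25 with probe sets of relative error under 30%.

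Toward the PPP-labelled array the 15 largest differences took in genes of several kinds, and no shared theme was tested. CDH5, the cadherin of endothelial junctions, read 18.5 ± 5.4 (absent) on the HFR-labelled and 290.8 ± 11.8 MBEI on the PPP-labelled array, at least 15.7-fold higher. TAL1, a transcription factor of blood precursors, read 60.9 ± 5.3 and 827.5 ± 225.6 MBEI, 13.6-fold higher, and TWIST1, a mesenchymal transcription factor, was at least 16.4-fold higher. SHISA2, which holds back Wnt and FGF receptors, read 251.8 ± 20.1 and 1528.6 ± 11.5 MBEI, 6.07-fold higher. Matrix genes among the 15 were the gelatinase MMP2 (at least 9.37-fold) and the collagen COL5A2 (6.09-fold). The proprotein convertase PCSK5 was 10.8-fold higher, with 4 of 4 passing probe sets in that direction. The neuropeptide receptor NPBWR1 (at least 19.7-fold), the Iroquois factor IRX2 (at least 17.2-fold, log2 standard error 1.09), SLITRK4 (16.6-fold), AMER2 (at least 12.1-fold), the LIM protein FHL2 (11.1-fold), SH3BGR (10.4-fold), the cell adhesion protein CNTN4 (8.65-fold) and PKDCCB (at least 6.79-fold) made up the rest. Without probe sets of suffix s, x or a, SH3BGR had a log2 difference of 0.20, from a probe set absent on both arrays, in place of -3.38.

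Cardiac specification genes had a median below 0. Of 22 on the array 9 passed the filter and 7 of these lay below 0, with 3 at 2-fold or more higher on the PPP-labelled array and 1 on the HFR-labelled array. MYOCD, a coactivator of cardiac and smooth muscle genes, was at least 3.67-fold higher on the PPP-labelled array (67.6 ± 0.8 and 248.0 ± 12.3 MBEI). The heart field factors ISL1 (at least 2.70-fold) and HAND2 (at least 2.15-fold) were also higher there, as was NKX2-5 (at least 1.83-fold, 46.4 ± 3.1, absent, and 85.1 ± 4.6 MBEI). SRF, GATA5, GATA6 and MEF2A had log2 differences of -0.97, -0.62, -0.54 and 0.06. With NKX2-5 these lie outside the naming rule and were chosen after their values were seen. MESP1, a bHLH factor of nascent mesoderm, was 2.60-fold higher on the HFR-labelled array (2301.2 ± 11.8 and 883.7 ± 27.9 MBEI). The list's median log2 difference was -0.88, below each of the 10000 medians of random lists (percentile 0), and -0.11 (percentile 2.16) without the level filter.

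Contractile genes of the heart divided in the same way. Of 9 that passed (20 on the array), 3 were at 2-fold or more higher on the PPP-labelled array, namely the myosin light chain MYL4 (4.71-fold, 411.7 ± 5.5 and 1938.6 ± 76.5 MBEI), cardiac actin ACTC1 (2.93-fold) and troponin T TNNT2 (2.29-fold). MYL3 was at least 9.59-fold higher on the HFR-labelled array, at 210.0 ± 77.9 against 21.9 ± 3.8 MBEI (absent). The median was -0.54, at percentile 0.235. It was -0.07 without the level filter and the mean was -0.35, both within the range of random lists (percentiles 7.05 and 6.25).

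Anterior endoderm and hypoblast genes went both ways. Of 18 that passed (23 on the array), 6 were at 2-fold or more higher on the PPP-labelled array, namely SHISA2, the Wnt receptor FZD5 (4.72-fold), CER1, the homeobox factors HHEX (3.08-fold) and GSC (3.00-fold), and the Wnt antagonist SFRP1 (2.17-fold). The head factor OTX2 had a log2 difference of -0.88 (225.2 ± 8.7 and 415.5 ± 4.7 MBEI), and HESX1 was at least 1.59-fold higher on the PPP-labelled array. Both were chosen after their values were seen, while FOXA2, FRZB and GDF3 had log2 differences of -0.05, -0.11 and -0.27. In the other direction lay 4 genes, the tight junction protein CLDN1 (8.02-fold, 6219.4 ± 123.7 and 775.7 ± 61.5 MBEI), the endoderm factor HNF4A (at least 5.92-fold), the Nodal antagonist LEFTY1 (at least 3.30-fold) and the epithelial adhesion molecule EPCAM (2.88-fold). The median was -0.60 at percentile 0, and the mean -0.35. On the same arrays the extraembryonic list lay the opposite way, with a median of 2.62, and the poly-A spike-ins had a median of -1.49.

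Of 30 blood and endothelial genes on the array 14 passed, and 13 of these lay below 0. Of the 14, 6 were 2-fold or more higher there and 0 on the HFR-labelled array. Besides CDH5, TAL1 and HHEX these were the VEGF receptor FLT1 (at least 4.62-fold, 52.6 ± 4.0 and 243.0 ± 2.8 MBEI), the endothelial factor SOX7 (4.02-fold) and podocalyxin PODXL (2.45-fold). KDR, the main VEGF receptor of hemangioblasts, had a log2 difference of -0.78 (849.6 ± 22.4 and 1459.6 ± 15.2 MBEI), FLI1 of -0.68 and SOX17 of -0.53. These were chosen after their values were seen, while EGFL7, the 1 passing member above 0, had 0.42. LMO2, a partner of TAL1 chosen after its values were seen, was absent on both arrays with the probe set that stood for it, and its other probe set read 44.2 ± 3.8 (marginal) and 501.3 ± 7.0 MBEI, at least 11.3-fold higher on the PPP-labelled array. The list's median was -0.73 at percentile 0, and -0.16 without the level filter, while the mean was -1.22. Without probe sets of suffix s, x or a, FLT1 was represented by a probe set absent on both arrays (-0.06 in place of -2.21), while its remaining probe set read 16.4 (absent) and 59.0 MBEI (present), a log2 difference of -1.85.

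Primitive streak genes went both ways. Of 18 that passed (24 on the array), 11 lay above 0, with 4 at 2-fold or more higher on the HFR-labelled array and 2 on the PPP-labelled array. WNT3A, a Wnt ligand of the streak, was 6.32-fold higher (1200.0 ± 33.0 and 189.8 ± 7.7 MBEI), WNT5B 3.79-fold, FGF3 at least 3.62-fold and the zinc finger factor SP8 at least 3.16-fold. MSGN1, a factor of presomitic mesoderm, had a log2 difference of 0.82 and TBXT of 0.95, while WNT8A, PDGFRA and CFC1 had -0.52, -0.42 and -0.33. Apart from TBXT, these were chosen after their values were seen, and 7 of the 18 lay below 0. FGF8, a streak FGF ligand, was at least 4.54-fold higher on the PPP-labelled array (62.2 ± 5.8, absent, and 282.1 ± 16.5 MBEI). The noncanonical ligand WNT11 was 2.45-fold higher there. WNT11 had a log2 difference of -0.68 in place of -1.30 with the median over its probe sets. The list's median was 0.28, at percentile 99.7, and 0.21 without the level filter, just inside the range of random lists (percentile 97.49).

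**Figure D2:**
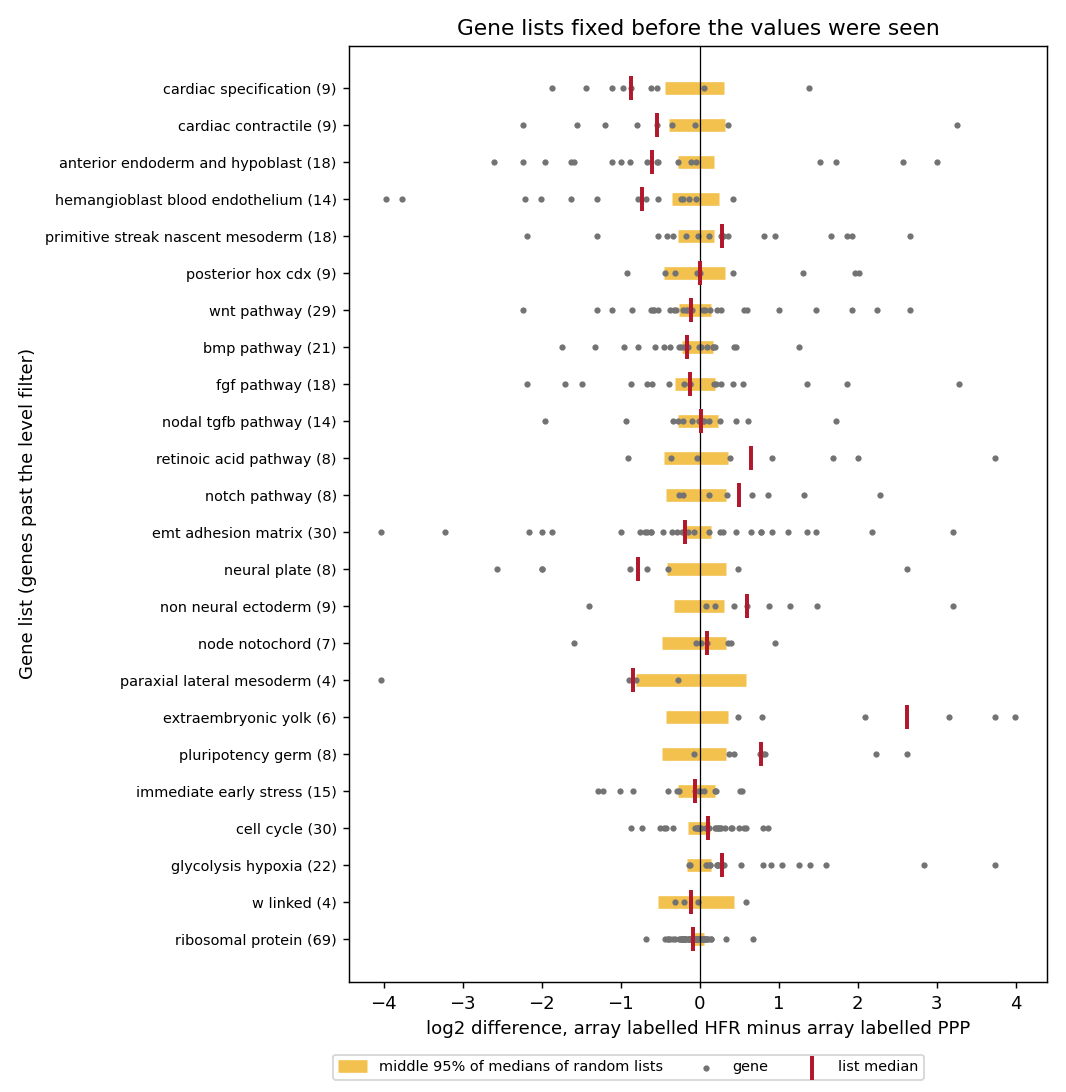
Log2 difference (HFR-labelled minus PPP-labelled) of genes past the level filter in each list (grey points), with the list median (red bar) and the middle 95% of medians of random lists matched on level (yellow). The cardiac, anterior, blood, neural plate, paraxial and ribosomal medians lie below that range, and the streak, retinoic acid, Notch, ectoderm, extraembryonic, pluripotency and glycolysis medians above it.

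Of the Hox and Cdx genes, which pattern the posterior body, 9 passed of 32 on the array. HOXA9 was at least 4.04-fold higher on the HFR-labelled array, CDX2 at least 3.89-fold (994.3 ± 104.2 and 255.3 ± 3.4 MBEI, absent) and HOXB1 2.47-fold. CDX4 had a log2 difference of -0.92 (1861.4 ± 69.2 and 3528.2 ± 36.6 MBEI). The median was 0.00 at percentile 63.2, within the range of random lists. It was 1.31 with the stricter level filter (percentile 99.96) and the mean was 0.44 (percentile 97.73), both above that range. The 1.31 is the value of HOXB1, the middle gene among those that the stricter filter left. The 0.00 is the value of HOXA6, a dim gene (114.9 ± 17.5 and 114.6 ± 13.2 MBEI).

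Signalling pathways divided by member. In the Wnt list 29 of 46 genes passed, with 5 at 2-fold higher on the HFR-labelled array and 3 on the PPP-labelled array. Besides WNT3A and WNT5B, the former were the R-spondin RSPO3 (4.73-fold, 1503.3 ± 57.9 and 318.1 ± 9.4 MBEI), the feedback inhibitor AXIN2 (2.77-fold, 1887.9 ± 59.3 and 682.1 ± 21.6 MBEI) and the Wnt deacylase NOTUM (2.00-fold), and the latter were FZD5, WNT11 and SFRP1. The median was -0.11 (percentile 30.5), while the mean was 0.05. Of 18 FGF genes that passed (31 on the array), 3 were 2-fold higher on each array, FGF19 (9.68-fold, 554.9 ± 24.1 and 57.3 ± 4.9 MBEI), FGF3 and FGF13 (2.56-fold) on the HFR-labelled one and FGF8, the decoy receptor FGFRL1 (at least 3.26-fold) and FGF18 (2.80-fold) on the other. Their median was -0.12 (percentile 32.9).

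In the BMP list 21 of 28 genes passed. MSX2, a homeobox target of BMP signalling, was 3.35-fold higher on the PPP-labelled array (442.6 ± 17.1 and 1481.3 ± 65.1 MBEI) and the ligand BMP5 2.51-fold, VSX1 at least 1.95-fold, and BMP7 was 2.39-fold higher on the HFR-labelled array. Without probe sets of suffix s, x or a, BMP7 was represented by a probe set absent on both arrays (0.20 in place of 1.26). The median was -0.17 (percentile 8.85), and -0.12 (percentile 0.99) without the level filter, below the range of random lists. Nodal and TGF-beta genes (14 of 19 passed) had CER1 at 2-fold higher on the PPP-labelled array and LEFTY1 on the HFR-labelled array. The activin receptor ACVR2A and the activin subunit INHBB had log2 differences of -0.93 and 0.61, and the list's median was 0.01 (percentile 65.1) with a mean of -0.04.

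The retinoic acid and Notch lists had medians above 0, with 3 of 8 and 2 of 8 passing members at 2-fold or more. Of all passing genes 8.11% reached 2-fold. Of 8 retinoid genes that passed (16 on the array), the dehydrogenases ALDH1A1 (at least 4.02-fold, 115.7 ± 47.8 and 28.8 ± 2.5 MBEI, absent) and RDH10 (3.22-fold, 2322.6 ± 16.7 and 720.7 ± 22.8 MBEI), and TTR, were 2-fold or more higher on the HFR-labelled array, and 0 on the other array. A further 3 of the 8 lay below 0, among them the retinoic acid binding protein CRABP1 (-0.91) and the retinaldehyde reductase DHRS3 (-0.36), both chosen after their values were seen. ALDH1A2, which makes retinoic acid in mesoderm, had a log2 difference of 0.91, while its other passing probe set read -0.08. The median was 0.65 (percentile 99.9). It was 0.39 with the stricter filter (percentile 96.65) and with the relative error under 30% (percentile 97.2), both within the range of random lists. With the median over probe sets and with the highest passing probe set it was also 0.39, but above that range (percentiles 99.2 and 98.2). Without the filter it was 0.33 (percentile 99.56). Of 8 Notch genes that passed (15 on the array), the ligand DLL1 was 4.85-fold higher on the HFR-labelled array (2355.0 ± 75.9 and 485.9 ± 3.5 MBEI) and the effector HES4 2.49-fold. NOTCH2 and HEY1 had log2 differences of 0.86 and 0.66, 2 of the 8 lay below 0, and the median was 0.50 (percentile 99.8).

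Adhesion and matrix genes of the epithelial to mesenchymal transition lay at both ends. Of 30 that passed (38 on the array), 5 were at 2-fold higher on each array. The epithelial cadherin CDH1 was 9.20-fold higher on the HFR-labelled array (850.4 ± 64.3 and 92.4 ± 27.0 MBEI), with the basement membrane collagens COL4A2 (4.54-fold) and COL4A1 (2.77-fold), CDH3 (2.57-fold) and the laminin receptor subunit ITGA6 (2.18-fold). On the PPP-labelled array TWIST1, MMP2, the mesenchymal cadherin CDH11 (4.48-fold), the CDH1 repressor ZEB2 (3.98-fold) and the fibrillar collagen COL1A2 (3.66-fold) were higher. The median was -0.18 (percentile 5.24), within the range of random lists, and below it at -0.28 with the median over probe sets, at -0.26 with the highest passing probe set and at -0.23 after quantile normalization. CDH3 had a log2 difference of -0.28 in place of 1.36 without probe sets of suffix s, x or a, from a probe set below the level filter, and COL4A2 of 0.66 in place of 2.18 with the median over its probe sets.

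Markers of other tissues that the pieces could hold also differed. Of 9 non-neural ectoderm genes that passed (19 on the array), CDH1, the claudin CLDN3 (2.80-fold) and the homeobox gene DLX5 (2.2-fold) were higher on the HFR-labelled array and DLX6 on the PPP-labelled array (at least 2.65-fold), with a median of 0.60 (percentile 99.98), 0.27 without the level filter and 1.01 with the stricter one. Neural plate genes (8 of 17 passed) had a median of -0.78 (percentile 0), with the zinc finger factor ZIC2 (5.93-fold, 233.4 ± 44.6 and 1385.2 ± 101.9 MBEI), GBX2 (4.00-fold) and ZEB2 higher on the PPP-labelled array and SOX3, a factor of the epiblast and neural plate, 6.15-fold higher on the HFR-labelled array. The neural plate median was 0.01 without the level filter and -1.44 without probe sets of suffix s, x or a. Of 7 node and notochord genes that passed (12 on the array) GSC alone reached 2-fold, FOXD1 was at least 1.32-fold higher on the HFR-labelled array, NOTO and TBXT had log2 differences of 0.36 and 0.95, and the median was 0.10 (percentile 78.6). Paraxial and lateral mesoderm genes (4 of 15 passed) had a median of -0.85 (percentile 1.86), or -0.02 without the filter and -2.46 with the stricter one, while the mean was -1.50. The -2.46 is the midpoint of TWIST1 (-4.03) and PRRX1 alone and describes no wider shift of the list. TWIST1 was at 2-fold and PRRX1 at least 1.85-fold higher on the PPP-labelled array (PRRX1 log2 difference -0.89, standard error 0.43). FOXC2 was at least 1.21-fold higher there, but its log2 difference of -0.28 had a standard error of 0.21, so its direction is uncertain. MEOX1 had a log2 difference of -0.81.

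Among the lists, genes of yolk and extraembryonic endoderm had the largest median with the level filter, though not without it. Of 22 on the array 6 passed, and 4 of these were 2-fold or more higher on the HFR-labelled array and 0 on the other. Besides APOA1 and TTR these were the fibrinogen chains FGB (8.88-fold, 271.7 ± 2.4 and 30.6 ± 3.5 MBEI) and FGG (at least 4.27-fold). Cathepsin CTSB and transferrin TF, chosen after their values were seen, had log2 differences of 0.78 and 0.49. The symbol RBP4 was preset in this list and in the retinoid list, but it was not matched to RBP4A. RBP4A, which was higher on the HFR-labelled array, is therefore in neither list's counts or median. The list's median was 2.62, above each of the 10000 random medians (percentile 100), 0.39 without the level filter and 1.44 with probe sets of relative error under 30%.

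Control probe sets differed between the arrays as well. The poly-A spike-ins, RNAs added before amplification, were lower on the HFR-labelled array for 36 of 36 probe sets, with a median log2 difference of -1.49 (range -2.13 to -0.87), which is 2.81-fold. Hybridization spike-ins, added after amplification, were lower for 27 of 27 probe sets with a median of -0.24 (range -0.41 to -0.16). The 36 poly-A probe sets read 4 transcripts (dap, lys, phe and thr), and 33 were called present on the HFR-labelled array. The hybridization probe sets likewise read few transcripts, so probe sets of a class are not separate observations. The ratio of 3 prime to 5 prime signal was 4.92 on the HFR-labelled and 5.08 on the PPP-labelled array for ACTB, 3.03 and 3.54 for EEF1A, and 1.96 and 2.79 for GAPDH. For the poly-A transcripts it was 36.6 and 21.4 (dap), 7.61 and 5.13 (lys), 7.13 and 4.69 (phe), and at least 13.0 against 13.0 for thr, whose 5 prime probe set was called absent on the HFR-labelled array.

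**Figure D3:**
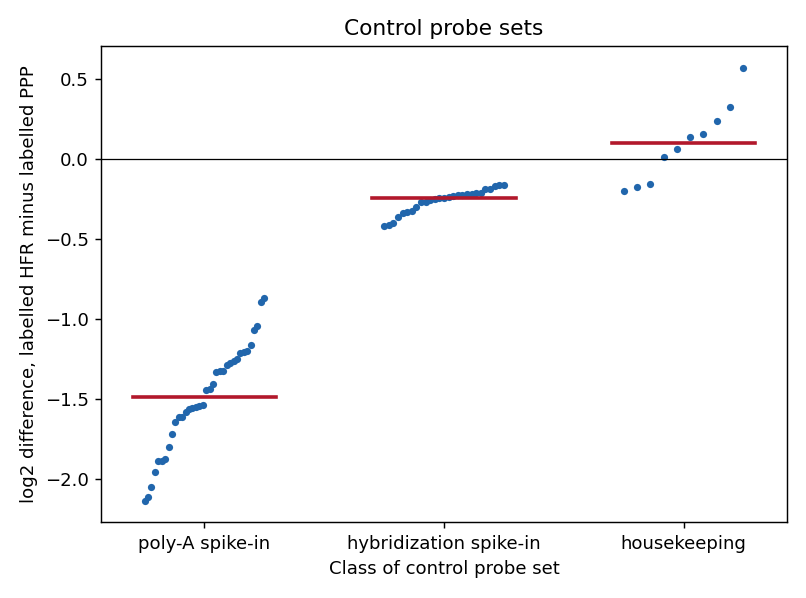
Log2 difference (HFR-labelled minus PPP-labelled) of each control probe set (points) by class, with class medians (red lines). The poly-A spike-ins lie between -2.13 and -0.87, below the hybridization spike-ins, which lie between -0.41 and -0.16.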

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

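All tests of explanations in this part were chosen only after the result was seen. Reporter probe sets were outside the comparisons of the report, and the labels give no array without the plasmid as a control. Of 57 reporter probe sets, 4 were called present on the PPP-labelled array and 0 on the HFR-labelled array, and 2 of the 4 lay above the level filter of 70.8 MBEI. RPTR-Gga-U43284-1_s_at was called present on the PPP-labelled array at 2866.4 MBEI with a model standard error of 1379.8, and absent on the HFR-labelled array at 123.7. The annotation used here does not name its target. Whether it reads the electroporated EGFP, in which case the signal would also go against the labels, was not settled here. RPTR-Gga-J01636-1_at was called present on the PPP-labelled array at 101.8 MBEI, and absent on the HFR-labelled array at 121.1, the brighter value.

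The heart and anterior endoderm lists had medians toward the array labelled posterior streak, and the streak list toward the array labelled heart forming region. A regional difference as labelled would put the pooled cardiac specification and anterior lists (26 genes) above 0, and their median log2 difference was -0.77, outside the range of random lists (-0.245 to 0.145), which restates the pattern on lists fixed beforehand and is no separate evidence, and without the level filter the cardiac specification median was -0.11. Scaling that varies with level is argued against, as the median was -0.81 after a loess trend was subtracted. An exchange of the labels needs streak genes out of place as well. Their median of 0.28 lay above the random range (0.21 and just inside it without the level filter). The posterior Hox and Cdx list was also set to be out of place. Its median was 0.00 within the random range (1.31 and above it with the stricter filter). The 0.00 is the value of HOXA6, a dim gene (114.9 and 114.6 MBEI), and the 1.31 that of HOXB1. As a single gene set each median, this list counts neither for nor against an exchange. An exchange may be the explanation and stays open. FGF8, WNT11 and CDX4, among others, lay the other way, and 5 of the 26 pooled genes were at 2-fold higher on the HFR-labelled array. The blood and endothelial list (median -0.73, with 13 of 14 passing genes toward the PPP-labelled array) was not part of this weighing. Whether that list goes with the labels or with an exchange was not tested. The mapping was kept as labelled.

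All 6 yolk and extraembryonic genes past the filter lay toward the HFR-labelled array, 4 of them at 2-fold or more. Probe error within the arrays is argued against as the whole cause, since with probe sets of relative standard error under 30% the list's median was 1.44, at percentile 99.99 among random lists, although TTR was then at 0.54. RNA of extraembryonic endoderm in the excised piece could raise the list, and its median of 2.62 restates the pattern and is no separate evidence for it, as 1 array per tissue cannot separate such RNA from expression within the piece or from exchanged labels. APOA1 read 4249.7 and 267.9 MBEI on the HFR-labelled and PPP-labelled array, while TF and CTSB differed by 0.49 and 0.78. Pieces were selected by hand for EGFP and shape per the labels, and of the 6 genes TTR is also in the retinoid list.

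Poly-A spike-ins were lower on the HFR-labelled array by a median of -1.49. Overall brightness is argued against, since hybridization spike-ins differed by -0.24. Shorter amplified RNA on that array stays open as a part of the cause. The 3 prime to 5 prime ratio was lower there for the 3 housekeeping genes (median log2 difference -0.22) and higher for dap, lys and phe. The 3 prime probe sets of the poly-A spike-ins were also lower there, between -1.54 and -0.87. A loss of 5 prime signal alone is therefore argued against as the whole cause. Less spike-in RNA relative to sample RNA could account for the gap of -1.25 between both kinds of spike-in, and cannot be told apart from a difference in amplification, as no value separates input from yield. The difference between the tissues in RNA content per cell was not tested.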

How the results depend on the processing

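The settings with a highest passing probe set, a relative error under 30% and poly-A spike-ins set equal were chosen only after the results were seen, and the others before. No paired analysis was possible because each tissue had 1 array and the labels pair none. Counts of genes at 2-fold stayed between 219 and 331 (HFR-labelled) and between 221 and 376 (PPP-labelled) under the other scalings, filters and probe set choices, and 0 of the genes counted in these settings were counted in the opposite direction in the report. A 1.5-fold threshold gave 697 and 963 genes and a 4-fold threshold 73 and 44, by construction. Setting the poly-A spike-ins equal gave 6157 and 17, since it moved the median of all genes to 1.44. Without the level filter the medians were -0.107 (cardiac specification), -0.069 (contractile), -0.159 (blood and endothelial), 0.211 (streak), -0.124 (BMP), 0.333 (retinoic acid), 0.268 (ectoderm), -0.021 (paraxial), 0.387 (extraembryonic) and 0.438 (pluripotency), the neural plate median reversed to 0.013, and 55.2% of 2-fold genes had all probe sets in one direction, against 100% under the stricter filter. The filters changed no gene's value, so these moves came from the genes and probe sets that they let in or left out. Those let in were not called present on their brighter array or lay under 70.8 MBEI there. The stricter filter gave 1.307 (Hox and Cdx, the value of HOXB1), 0.388 (retinoic acid), 1.006 (ectoderm) and -2.461 (paraxial, from TWIST1 and PRRX1 alone). Means in place of medians gave -0.347 (contractile), -0.353 (anterior), -1.218 (blood and endothelial), 0.444 (Hox and Cdx), -1.502 (paraxial) and 0.730 (glycolysis). Medians over probe sets gave 0.388 (retinoic acid), -0.285 (adhesion and matrix) and 0.391 (pluripotency), the highest passing probe set 0.388 and -0.257 for the first 2 of these, and a relative error under 30% 0.388 (retinoic acid) and 1.438 (extraembryonic). Median centring moved the glycolysis median to 0.212 and the ribosomal median to -0.159, by the constant it subtracts, and quantile normalization gave -0.226 (adhesion and matrix) and -0.061 (ribosomal). Without probe sets of suffix s, x or a the neural plate and ribosomal medians were -1.438 and -0.129, and of the named genes at 2-fold CDH3 (-0.28) and SH3BGR (0.20) reversed, since dimmer probe sets then stood for those genes. Among named genes under 2-fold, RPS6KB1 (-0.31), SALL4 (-0.22) and UBAP2L2 (-0.28) changed sign in that setting, and CCBE1 did so with a pseudocount (-2.36) and where passing probe sets alone were used (-3.11). Of the list values 33 moved, 1 reversed and 254 were the same, meaning within the range from resampling the list's members, on the same side of the random range and, if outside that range, within 1.5 times. Of 1384 values of 127 named genes, 1317 lay within 2 standard errors, 65 moved and 2 reversed, where reversal was counted for the 98 genes at 2-fold alone. Many of these values were fixed in advance. The level filters and the series' value table could not change a gene's value, nor could other probe set choices for genes with a single probe set. The series' value table could not move a list median either. These counts are therefore no measure of robustness. Signal over background limits the dim genes, as present probe sets had a median of 211 and 195 MBEI and absent ones 45.5 and 41.9.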

Other observations

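No tests of explanations were run for the values in this part. Of 26 genes of glucose uptake, glycolysis and hypoxia on the array 22 passed the level filter, and 20 of these lay above 0. Of the 22, 6 were at 2-fold or more higher on the HFR-labelled array and 0 on the other array. Besides LDHA (13.3-fold) these were the glucose transporters SLC2A14 (7.13-fold, 3312.5 ± 139.4 and 464.9 ± 4.8 MBEI) and SLC2A1 (2.64-fold), hexokinase HK1 (3.03-fold), the peptide hormone ADM (2.39-fold) and the pyruvate dehydrogenase kinase PDK1 (2.06-fold). The list's median log2 difference was 0.28, at percentile 99.95 among random lists, and the mean 0.73. Pluripotency and germ cell genes (8 of 15 passed) had a median of 0.78 (percentile 99.98), 0.44 without the level filter and 0.39 with medians over probe sets, with 2 at 2-fold or more higher on the HFR-labelled array and 0 on the other, SOX3 (6.15-fold) and the receptor KIT (at least 4.68-fold, 111.5 ± 5.7 and 23.8 ± 2.9 MBEI, absent). The DNA methyltransferase DNMT3B and the factor SALL4 had log2 differences of 0.83 and 0.80, while another passing probe set of each read -0.04 and -0.22, and the medians over their probe sets were 0.39 and 0.29.

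Immediate early and stress genes had 3 of 15 passing members (19 on the array) at 2-fold or more higher on the PPP-labelled array, JUN (2.44-fold), EGR1 (2.33-fold) and GADD45A (2.02-fold), and ATF3 had a log2 difference of -0.84. The list's median was -0.06 (percentile 45.6). Of 30 cell cycle genes 0 reached 2-fold. CCND1, PLK1, CCND3 and PCNA had log2 differences of 0.86, 0.80, -0.87 and -0.73, and the median was 0.11 (percentile 94.2). Without probe sets of suffix s, x or a CCND3 was at -0.01, from a probe set absent on both arrays. Ribosomal protein genes (69 of 76 passed) had a median of -0.09 (percentile 0.53), -0.16 after median centring and -0.06 within the random range (percentile 7.55) after quantile normalization, with 0 at 2-fold, and RPL31, RPL34 and RPL22 had log2 differences of -0.68, -0.44 and -0.40. RPS6KB1, an S6 kinase taken in by its symbol, had 0.68 with a second passing probe set at -0.31. Of 5 genes of the female-specific W chromosome 4 passed, and HINTW read 8498.9 ± 200.5 and 8662.1 ± 191.5 MBEI on the HFR-labelled and PPP-labelled array. UBAP2L2, UBE2R2L and LOC374195 had log2 differences of 0.58, -0.20 and -0.31, and the list's median was -0.11 (percentile 37.5) with a mean of 0.01. Without probe sets of suffix s, x or a UBAP2L2 was at -0.28, from a probe set below the level filter. Over all 10 passing genes on chromosome W the median was 0.09, of opposite sign to the list. The 344 passing genes on chromosome Z had a median of -0.09, against -0.05 for 6974 autosomal genes.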
